A study of Elaeis guineensis with 9 samples.

How the data were processed

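Leaf RNA of the African oil palm, Elaeis guineensis, was profiled by RNA sequencing in 9 libraries. Per the labels, the palms were of the Tenera cultivar, stood in 1 field, were 7 years old and had 4 years of yield records, and leaf tissue came from frond 17. Each library belonged to 1 of 3 yield classes (low, medium or high oil yield) and to 1 of 3 populations (Deli x LaMe, Deli x Yangambi or Deli x SP540, also called LaMe, Yangambi and SP540 here), and each combination was represented by 1 library. Yield class and population were both taken from the labels of each sample. The labels do not say whether a library came from a single palm or from a pool, nor whether libraries were made or sequenced in batches, so p-values measure the spread between these libraries and a batch difference could not be separated from the groups. RNA was extracted with a Norgen kit and libraries were made with a TruSeq mRNA kit, per the labels' protocols.

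The deposited table gives transcript abundance in TPM for 51490 RefSeq transcript rows, of which 32 are curated mRNA models, 43433 are predicted mRNA models and 8025 are predicted non-coding models. TPM is the share of transcripts of one kind, corrected for transcript length and scaled to a total of 1000000 per library. The table is named as counts, but the values hold decimals and every deposited TPM column sums to 1000000. The submitters' processing notes name the tools fastp (read trimming), kallisto (transcript quantification without alignment) and DESeq2, without versions or the order of steps; the transcript set and the genome build are not given in the sources used here. A TPM table keeps no sequencing depth. The depth of each library is therefore unknown, no counting interval can be given, and a value of 0 is described as listed at 0. kallisto divides reads that match several transcripts among them by estimation, so values of near-identical copies are uncertain.

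Transcript rows were joined to a RefSeq gene table of assembly EG11 by accession without the version number, which paired 31716 rows (61.6%) with 21914 genes, whereas 1009 rows matched with the version number included. The assembly behind the deposited table may differ, so the gene table was used only for names and for which genes are neighbours. TPM values of rows of one gene were summed, and unpaired rows were kept as single features, which gave 41688 features, 5324 of them listed at 0 in all 9 libraries. A feature is thus a gene sum or an unpaired transcript row. Paired rows held 77.1 to 79.3% of TPM per library. Features with at least 1 TPM in at least 3 libraries were tested. These were 25145 features, 15299 of them paired with a gene, and they held at least 99.6% of the TPM of each library.

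Values were tested as log2(TPM + 1), and all differences are on that scale, which understates the change of features at low TPM. Linear models with population and yield class as additive terms were fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with a trended and robust prior variance (statmod 1.5.0), 4 residual degrees of freedom and 3.04 to 3.08 prior degrees of freedom. With 1 library per combination an interaction between yield class and population could not be fitted. Any such interaction is part of the residual spread, so the tests address only yield differences shared by the populations, and population differences shared by the yield classes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested features, with a threshold of 0.05, and a feature past it is said to be called. Mean ± SD values are TPM over the 3 libraries of a group (n = 3). Shares of variance were tested by exact permutation of population labels within yield classes, and of yield labels within populations, over 216 arrangements, which cannot give a p-value below 0.0278. Differences in library composition were tested by exact permutation in the same way. Correlations of ratios were computed across features, which are not independent replicates.

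The comparisons, the additive design, the rule for named features and most alternatives were fixed before the data were examined, on the assumption that the table held counts. The quasi-likelihood count test planned then was replaced by limma on log2 values, and count normalizations and count tests were not run. The minimum of 1 TPM in 3 libraries was set after the values were seen, following an exploratory fit of gene and transcript features with and without a filter. The summing of rows per gene had been planned. The rule allowed at most 2 features up and 2 down per comparison where no product descriptions were at hand: features past the threshold, with a mean of at least 5 TPM and the same direction in all 3 matched pairs of libraries, ordered by size of difference. Where fewer than 5 features passed, those with the smallest p-values were named as not passing. The 33 gene lists fixed beforehand (among them photosynthesis, lipid, hormone, stress, flowering and other-tissue lists) were defined on product descriptions, which were not used here. Matched on gene symbols and synonyms alone, only 2 lists found a gene, IAA1 for auxin response and the aquaporin AQP for mineral transport. Other genes belong to listed families by their known function, such as the MADS-box genes, CAT2, MnSOD and RPL27, but their symbols do not hold the words the lists search for. As matched, 0 lists reached 5 tested genes, so no list was tested. In their place, every gene of the table with a symbol or synonym other than a locus number was described (31 genes, 21 of them tested). This panel was defined after values had been seen, by a rule that does not use them.

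The fit was tested on simulated values for the 25145 features with variances drawn from the fitted prior. This simulation was revised once, because an earlier form drew from variances that were too small. Features varied independently in it, with no group difference beyond the stated changes. Changed features were drawn only from those with a mean log2(TPM + 1) above 2, so recovery at lower levels was not examined. With 50 features changed per size, the test recovered 34% of features changed by 1 on the log2 scale, 86% at 2, 88% at 3 and 92% at 4 for high against low yield, and 16%, 76%, 92% and 96% for Deli x Yangambi against Deli x LaMe. Beside the changed features, 13 unchanged ones were among 163 calls (7.98%) in the first of these comparisons and 4 among 144 (2.78%) in the second. With 500 features changed per size, 61.4% and 58.6% of changes of 1 were recovered, so the share recovered depends on how many features change. With no feature changed 0 were called in each comparison. The alternatives were median-of-ratios scaling, no filter, a mean of at least 1 TPM, a prior variance without the robust step, no covariate, only the 6 libraries compared, each population or yield class left out, transcript rows, and each library left out in turn, with other pseudocounts, the most variable features or the more abundant features for variance shares and ratios. Those chosen after seeing the data were pseudocounts of 0.1 and 5 for the tests, at least 5 TPM in 3 libraries, a prior variance without trend, paired genes only, and features with identical values counted once. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.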

Results

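The series measured transcript levels in leaves of oil palm, the tropical oil crop Elaeis guineensis, from palms grouped by oil yield and by genetic population. Tenera is the thin-shelled hybrid fruit form that is grown commercially. There were 9 libraries, 1 for each combination of 3 yield classes and 3 populations, so that each yield class and each population held 3 libraries. Depth is unknown, because TPM values do not keep it. Between 33581 and 37060 of the 51490 transcript rows were above 0 in a library, and 22529 to 23806 features reached 1 TPM. Both numbers were highest in the medium-yield Deli x SP540 library. The number of features at 1 TPM was 23296 ± 442 (SD, n = 3) in Deli x SP540, 22738 ± 253 in Deli x LaMe and 22727 ± 111 in Deli x Yangambi, a difference that an exact permutation test did not separate (p = 0.167, adjusted p = 0.815 over the family of composition measures). The share of TPM held by the 10 most abundant features of a library lay between 12.4% and 15.4%.

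The leaf profile was led by LOC105041203 at 28584 ± 2148 TPM (SD, n = 9) and LOC105046370 at 28096 ± 3106 TPM. XM_010925610.2 followed at 25337 ± 9988 TPM, with a range of 16075 to 46866. Among genes with a name, CAT2, a catalase that breaks down hydrogen peroxide, stood 8th of all features at 5086 ± 1247 TPM. The aquaporin AQP, a membrane water channel, was at 599 ± 98.8 TPM, the elongation factor gene EF1 at 547 ± 117 TPM, and the ribosomal protein gene RPL27 at 129 ± 17.4 TPM. GPAT, a glycerol-3-phosphate acyltransferase that starts glycerolipid assembly, was at 123 ± 14.4 TPM and the actin gene ACT1 at 30.3 ± 5.72 TPM. The 10 genes with a name that were not tested stayed under 1 TPM in all 9 libraries. They were the MADS-box genes AG2, AGL2-2, AGL2-3, GLO2 and SQUA1, CHI2 and LIP1, and, listed at 0 in all 9, AGL2-5, GLO1 and the embryogenesis regulator BBM. Another MADS-box gene, DEF1, was measured at 4.03 ± 1.56 TPM.

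The first question posed by the labels is whether leaf transcript levels follow yield class or population. The libraries grouped by population. Each of the 9 libraries had its highest correlation with a library of its own population, and 0 of 9 with one of its own yield class. Pearson's r of log2 values across features was on average 0.933 between libraries of the same population (range 0.918 to 0.947), 0.914 between libraries of the same yield class and 0.915 between libraries that shared neither. The first principal component (22.6% of variance) placed the LaMe libraries at one end and the Yangambi libraries at the other, and the second (15.7%) set the SP540 libraries apart. The third (13.0%) spread the Yangambi libraries, with scores of 66.6 for low, -55.7 for medium and -10.9 for high yield. Population accounted for 37.9% of the variance, against a mean of 26.6% over rearranged labels (exact permutation p = 0.0278, the smallest possible). Yield class accounted for 20.3%, against a mean of 20.7% over rearranged labels (exact permutation p = 0.778).

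**Figure D1:**
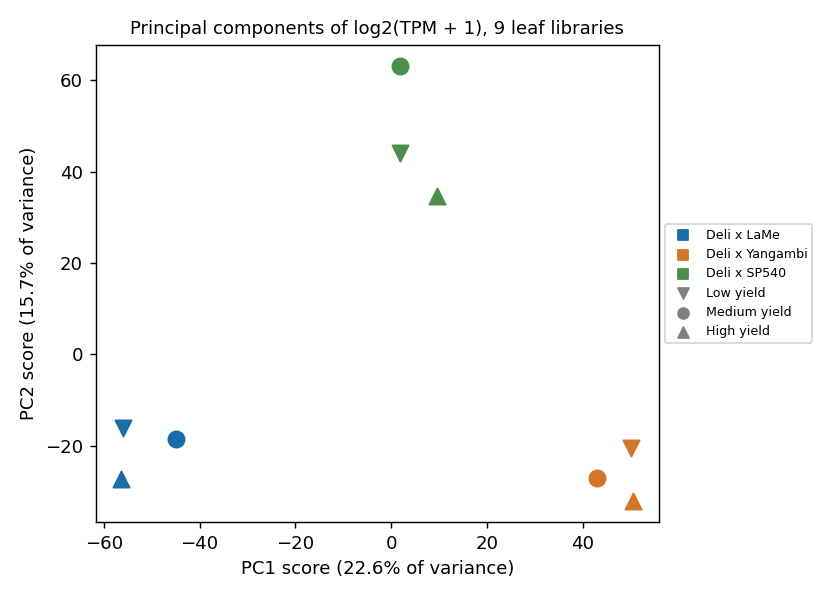
Scores of the 9 leaf libraries on the first and second principal components of log2(TPM + 1), with colour for population and marker shape for yield class; PC1 holds 22.6% and PC2 15.7% of the variance. The 3 libraries of each population lie together, and the 3 libraries of each yield class are spread over the plot.

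High yield was then compared with low yield across the 3 populations. No feature passed the test, and those named are the ones with the smallest p-values among features with a mean of at least 5 TPM and the same direction in all 3 populations. XM_029262294.1 was measured at 239 ± 160 TPM in high-yield and 72.2 ± 36.3 TPM in low-yield libraries, a log2 difference of 1.55 (SE 0.217). It was itself called in the joint test for population (adjusted p = 0.0336), with 30.9 to 66.5 TPM in Yangambi and 99.0 to 383 TPM in SP540 libraries. LOC105033645 was at 313 ± 63.1 and 119 ± 13.3 TPM, a difference of 1.37 (SE 0.223). In the other direction, LOC105057855 was measured at 5.92 ± 0.389 TPM in high-yield and 20.5 ± 8.14 TPM in low-yield libraries, and XM_029261155.1 at 2.49 ± 2.15 and 13.6 ± 6.58 TPM. All 4 had a limma adjusted p of 0.986. Of the 25145 features tested, 0 passed an adjusted p of 0.05 in limma, the only test run, and 1147 had an unadjusted p under 0.05, where 1257 are expected by chance. The lowest adjusted p, 0.552, belonged to XM_010907930.2, which has a mean of 4.91 TPM and was named after its values were seen (9.0 ± 1.25 TPM in high-yield and 0.463 ± 0.403 TPM in low-yield libraries, log2 difference 2.81, SE 0.285). The median unadjusted 95% interval of a difference reached 0.627 to either side on the log2 scale. In simulated values for this comparison, with 50 features changed per size, changes of 1 passed the adjusted threshold in 34% of cases. The simulated changes did not cover features of low level. Without the low-yield Yangambi library 1 feature passed, XM_029262365.1, which was named after its values were seen. It was at 64.4 TPM in that library, 1.87 and 2.23 TPM in the low-yield LaMe and SP540 libraries, and 35.8 to 75.6 TPM in the medium-yield and high-yield libraries.

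None of the 21 tested genes with a name passed for high against low yield, either over all features or when adjusted over the list alone, and 0 of them had an unadjusted p under 0.05. MnSOD, a manganese superoxide dismutase that removes superoxide, was measured at 170 ± 58.6 TPM in high-yield and 93.4 ± 15.1 TPM in low-yield libraries (log2 difference 0.81, SE 0.354, limma adjusted p = 0.581 over the list alone and 0.986 over all features). dxs, the entry enzyme of plastid isoprenoid synthesis, was at 10.1 ± 6.38 and 4.53 ± 1.93 TPM (0.84, SE 0.542). AQP was at 539 ± 59.4 TPM in high-yield and 654 ± 84.8 TPM in low-yield libraries. GPAT was at 118 ± 18.3 and 121 ± 15.5 TPM, a log2 difference of -0.04 (SE 0.144). For some genes with a name, but not for AQP or GPAT, the outcome over the list alone depended on the Yangambi libraries. With LaMe or SP540 left out, none passed over the list alone (lowest limma adjusted p 0.807 and 0.728). With Yangambi left out, CHAC1 (-0.70, SE 0.122), dxs (1.67, SE 0.350), MnSOD (0.99, SE 0.212) and EF1B (-0.67, SE 0.158) passed when adjusted over the list alone. Their limma adjusted p lay between 0.0375 and 0.0423, but they did not pass over all features (0.742). Without the high-yield Yangambi library alone, CHAC1 and dxs passed over the list (0.0240 each).

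For medium against low yield no feature passed the test. By the same rule of smallest p-values, XR_003799624.1 and XM_029266328.1 are named with higher values in medium-yield libraries, and XM_029263290.1 and XM_010934298.3 with lower values. XM_010934298.3 was measured at 16.9 ± 22.3 TPM in medium-yield and 142 ± 46.4 TPM in low-yield libraries, a log2 difference of -4.02 (SE 0.795, limma adjusted p = 0.9995). XM_029266328.1 was at 12.9 ± 7.43 TPM in medium-yield and at most 0.190 TPM in each low-yield library, a difference of 3.53 (SE 0.598). The limma test called 0 of 25145 features, 841 had an unadjusted p under 0.05, and the lowest adjusted p was 0.9995. Without the low-yield Yangambi library XM_029262365.1 passed here too (log2 difference 3.96, SE 0.174, adjusted p = 0.0117).

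High yield against medium yield gave a similar result. XM_029263518.1 was measured at 15.7 ± 5.42 TPM in high-yield and 0.866 ± 1.5 TPM in medium-yield libraries (log2 difference 3.39, SE 0.511), and XM_029264972.1 at 17.0 ± 5.40 and 5.50 ± 0.492 TPM. LOC105057855, also named for high against low yield, was at 5.92 ± 0.389 TPM in high-yield and 21.97 ± 3.27 TPM in medium-yield libraries (-1.72, SE 0.257), and XM_010926706.3 was at 6.32 ± 1.24 and 14.5 ± 2.38 TPM. None passed (limma adjusted p = 0.99993). The test called 0 features, and 1042 had an unadjusted p under 0.05. A joint limma test for any difference among the 3 yield classes also called 0 features, with 960 at an unadjusted p under 0.05.

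Whether a yield difference in 1 population recurred in another was examined across all 25145 features. The log2 ratio of high to low yield in LaMe had a Pearson correlation of -0.0056 with that in Yangambi and 0.0543 with that in SP540, and the ratio in Yangambi one of -0.0542 with that in SP540. Spearman's rho lay between -0.080 and 0.099. With features of at least 10 TPM on average, LaMe with SP540 gave a Pearson correlation of 0.135 and a Spearman's rho of 0.201, and Yangambi with SP540 gave -0.118 and -0.173. For comparison, the log2 ratio of Yangambi to LaMe correlated between yield classes at 0.257 to 0.307. The ratio of SP540 to LaMe did so at 0.182 to 0.225 and that of SP540 to Yangambi at 0.0899 to 0.173, and the highest of each reached 0.477, 0.393 and 0.307 with features of at least 10 TPM. These correlations are across features, which are not independent replicates, and no p-value was computed for them.

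**Figure D2:**
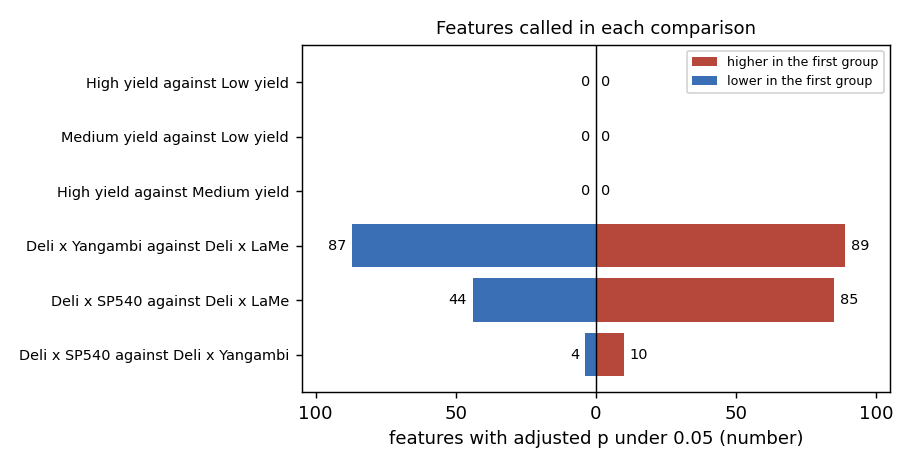
Number of features with an adjusted p under 0.05 in each pairwise comparison, drawn to the right for features higher in the first-named group and to the left for features lower in it. The 3 yield comparisons show 0 in both directions, and the 3 population comparisons show 176, 129 and 14 in total.

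Deli x Yangambi was compared with Deli x LaMe across the 3 yield classes. LOC105044074 was higher in Yangambi, at 67.8 ± 29.97 TPM against 0.144 ± 0.249 TPM in LaMe, a log2 difference of 5.85 (SE 0.303, limma adjusted p = 0.00084). LOC105058399 was higher too, at 59.6 ± 28.9 TPM (adjusted p = 0.0035), and was listed at 0 in all 3 LaMe libraries. The long non-coding RNA gene LOC114914524 was lower in Yangambi, at 0.0278 ± 0.0481 TPM against 53.8 ± 9.45 TPM (log2 difference -5.72, SE 0.248, adjusted p = 0.00050). LOC105043160 was also lower, at 37.3 ± 1.49 TPM in LaMe and at or close to 0 in each Yangambi library (-5.26, SE 0.244, adjusted p = 0.00051). In all, limma called 176 features, 89 higher and 87 lower in Yangambi, each in the same direction in 3 of 3 yield classes, with a median absolute log2 difference of 2.19 (range 0.69 to 5.85). The yield classes are the replicates of each population test, so a shared direction follows largely from the call and is no separate evidence. The lower group was under 1 TPM for 49 of the 176 features, and 34 were non-coding, a class that made up 9.85% of the features tested. No test of this class was run for the pairwise lists. With single libraries left out the number called ranged from 27 without the medium-yield LaMe library to 139 without the high-yield SP540 library. Intermediate values were 37 and 38 without the low-yield and high-yield LaMe libraries, 68, 55 and 38 without the low-yield, medium-yield and high-yield Yangambi libraries, and 117 and 104 without the low-yield and medium-yield SP540 libraries. It was 50, 18 and 12 without the low, medium and high yield class, 52 with only the 6 libraries compared, 117 with transcript rows, 64 with no filter and 429 with no covariate.

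Deli x SP540 also differed from Deli x LaMe, and 2 of the features named here are those named for Yangambi. LOC105044074 was at 73.8 ± 10.2 TPM in SP540, a log2 difference of 6.04 from LaMe (SE 0.303, limma adjusted p = 0.00066). LOC105044117 was at 73.8 ± 15.2 TPM against 0.340 ± 0.360 TPM (5.82, SE 0.307, adjusted p = 0.00074). LOC114914524 was lower in SP540, at 0.0220 ± 0.0382 TPM (-5.73, SE 0.248, adjusted p = 0.00051). XR_832332.2, a non-coding transcript, was at 42.8 ± 0.340 TPM in LaMe and listed at 0 in all 3 SP540 libraries (adjusted p = 0.018), and its call was lost in 9 of 24 alternatives, where the adjusted p reached 0.225. In all, 129 features were called, 85 higher and 44 lower in SP540, each in the same direction in 3 of 3 yield classes, with a median absolute log2 difference of 2.49 (range 0.76 to 6.04). The lower group was under 1 TPM for 45 of them, and 20 were non-coding, against 9.85% of the features tested. The number called was 39, 41 and 27 without the low-yield, medium-yield and high-yield LaMe libraries, 39, 35 and 44 without the SP540 libraries in the same order, and 90, 60 and 62 without the Yangambi libraries. It was 25, 16 and 17 without the low, medium and high yield class, 39 with only the 6 libraries compared, 74 with transcript rows, 75 with a pseudocount of 0.1, 54 with no filter and 235 with no covariate.

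The comparisons of Yangambi and of SP540 with LaMe called 76 features in common, all 76 with the same direction. Of these, 48 were lower in LaMe, where 0.301 would be shared by independent lists of 89 and 85 features, and 28 were higher in LaMe, where 0.152 would be shared. Both comparisons used the same 3 LaMe libraries, which cannot be split into parts of at least 2, so part of the excess may come from them. In 20 simulations without any effect, lists of the same sizes taken by smallest p-value shared a median of 17 features (highest 25) lower in LaMe and 12 (highest 18) higher in LaMe, as the shared libraries and shared variance estimates would give if features varied independently. The covariance of the log2 differences of the 2 comparisons across features was 0.208, against a mean of 0.119 and a highest value of 0.137 in the simulations, and their correlation was 0.590 against a mean of 0.504. Where features of a library vary together, the spread without any effect could be wider than simulated. The highest simulated values are therefore no bound, and the excess does not exclude the shared LaMe libraries as its source.

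**Figure D3:**
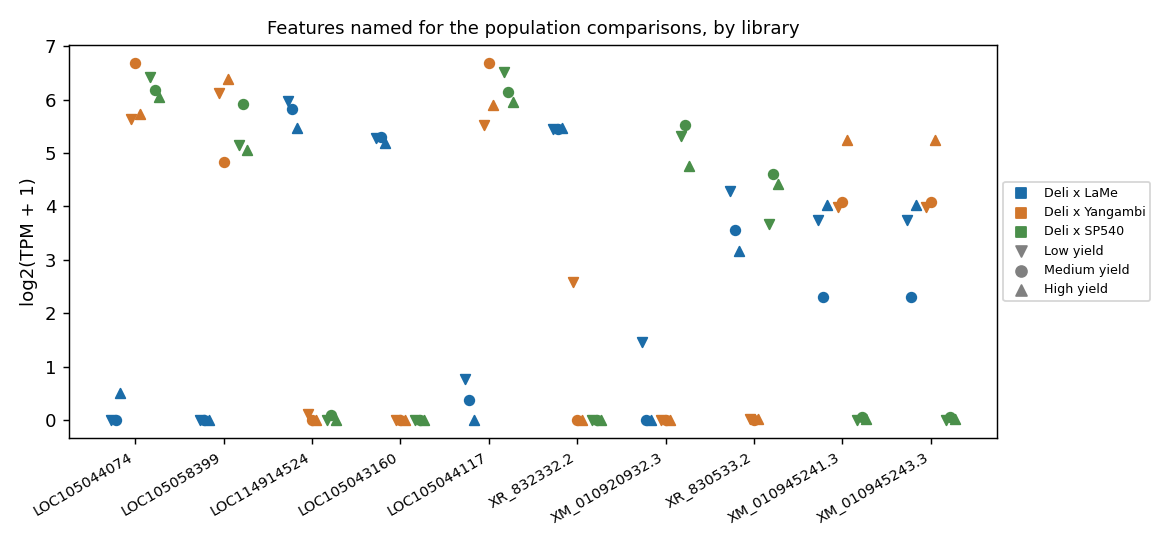
Level of each feature named for the population comparisons in each of the 9 libraries, as log2(TPM + 1), with colour for population and marker shape for yield class. LOC105044074, LOC105058399 and LOC105044117 lie near 0 in the 3 LaMe libraries and between about 27.4 and 102 TPM in the others; LOC114914524 and LOC105043160 show the opposite pattern.

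Deli x SP540 and Deli x Yangambi differed in fewer called features. At an unadjusted limma p under 0.05 the numbers lay closer together. They were 2649 here, 2857 for SP540 against LaMe and 3818 for Yangambi against LaMe, where 1257 are expected by chance. XM_010920932.3 was higher in SP540, at 36.8 ± 9.74 TPM, and below 0.001 TPM in each Yangambi library (log2 difference 5.21, SE 0.391, limma adjusted p = 0.0248). The non-coding transcript XR_830533.2 was at 18.5 ± 5.99 TPM in SP540 against 0.0093 ± 0.0087 TPM (4.22, SE 0.369, adjusted p = 0.0248). XM_010945241.3 and XM_010945243.3 were lower in SP540, at 0.0185 ± 0.0183 TPM against 22.6 ± 12.4 TPM (-4.41, SE 0.401, adjusted p = 0.0248), and had identical values in all 9 libraries, so that they amount to 1 measurement. The call was lost in 13 of 24 alternatives for XM_010920932.3 and in 15 of 23 or 24 for each of the other 3, with the adjusted p reaching 0.273. Limma called 14 features, 10 higher and 4 lower in SP540, each in the same direction in 3 of 3 yield classes. With only the 6 libraries compared, with no filter or without the medium yield class the number was 0, with transcript rows 1, without the high yield class 3, with pseudocounts of 0.1 and 5 it was 8 and 5, and with no covariate 60. It was also 0 without the high-yield LaMe library, the medium-yield Yangambi library or the high-yield Yangambi library. It was 1 without the low-yield LaMe or the low-yield SP540 library, 3 and 5 without the medium-yield and high-yield SP540 libraries, 8 without the medium-yield LaMe library and 21 without the low-yield Yangambi library.

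A joint limma test for any difference among the 3 populations called 153 features, with 3666 at an unadjusted p under 0.05. Leaving out single libraries gave between 33 (without the high-yield LaMe library) and 88 (without the low-yield Yangambi library). The other numbers were 46 and 47 without the low-yield and medium-yield LaMe libraries, 57 and 46 without the medium-yield and high-yield Yangambi libraries, and 59, 60 and 65 without the low-yield, medium-yield and high-yield SP540 libraries. It was 44, 1 and 11 without the low, medium and high yield class, 100 with transcript rows, 99 with a pseudocount of 0.1, 53 with no filter and 403 with no covariate. Non-coding features made up 22 of the 153 (14.4%) and 9.85% of the features tested (Fisher's exact test, odds ratio 1.54, p = 0.0749). Features that were not paired with a gene made up 79 of the 153 (51.6%) and 39.2% of those tested (Fisher's exact test, odds ratio 1.66, p = 0.0020, adjusted p = 0.0040 over the 2 classes). Fisher's test treats features as independent, but an unpaired feature is a single transcript row and a paired one is a gene sum. Among the called features, 2 unpaired rows had identical values, so the p-value is only a guide.

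Among the 21 tested genes with a name, 0 passed in any population comparison, over all features or adjusted over the list alone. EF1B, a translation elongation factor gene, was measured at 345 ± 67.2 TPM in Yangambi and 747 ± 114 TPM in LaMe (log2 difference -1.12, SE 0.247, limma adjusted p = 0.0547 over the list alone and 0.111 over all features). ADPRF, an ADP-ribosylation factor of vesicle traffic, was at 167 ± 4.86 TPM in Yangambi, 168 ± 10.9 TPM in SP540 and 117 ± 16.4 TPM in LaMe (adjusted p over the list alone 0.0547 and 0.109). CAT2 was at 3785 ± 381 TPM in Yangambi, 5781 ± 598 TPM in LaMe and 5691 ± 1381 TPM in SP540. NTF was the other gene with an unadjusted p under 0.05 for Yangambi against LaMe, where there were 4. ADPRF was the only 1 for SP540 against LaMe, and CAT2, M39A, CHAC1 and SAG were the 4 for SP540 against Yangambi. For Yangambi against LaMe, 2 of the 21 passed over the list alone without the high-yield Yangambi library and 1 without the low-yield SP540 library, and for SP540 against Yangambi 1 passed without the high-yield Yangambi library. In 7 other combinations of population comparison and alternative setting, 1 to 3 passed.

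**Figure D4:**
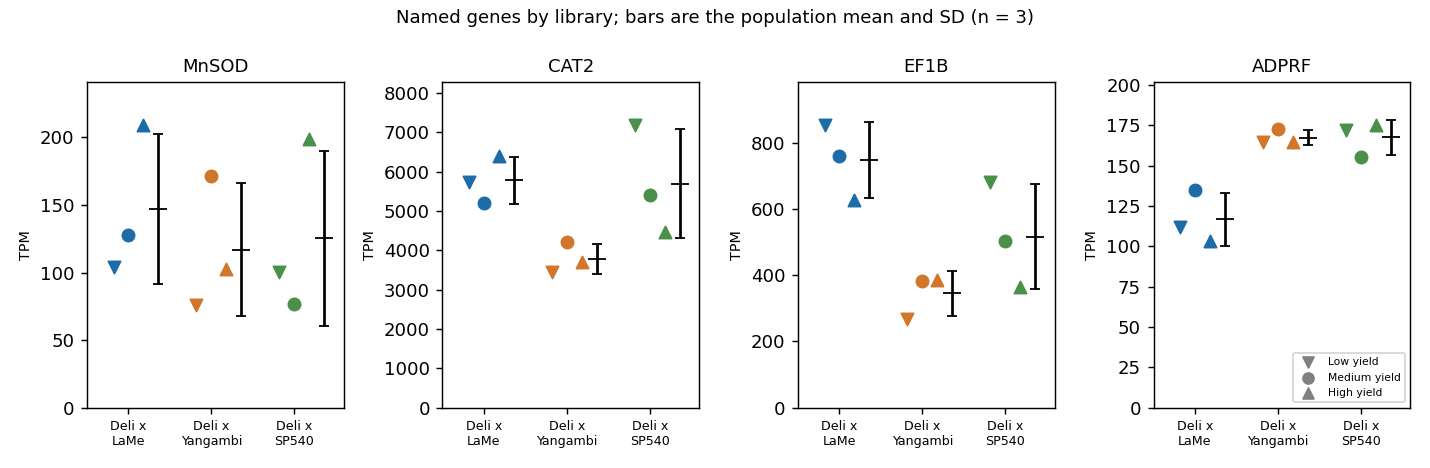
TPM of MnSOD, CAT2, EF1B and ADPRF in each library by population, with marker shape for yield class and bars for the population mean and SD (n = 3). EF1B lies at 345 ± 67.2 TPM in Yangambi and 747 ± 114 TPM in LaMe, and ADPRF at 167 ± 4.86 and 117 ± 16.4 TPM.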

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

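Features with at least 1 TPM in fewer than 3 libraries were left out of the tests, and 40 of them reached 10 TPM in 1 or 2 libraries, which is a signal outside the comparisons. A single library held between 0 and 9 of them. The highest was LOC105037797, at 367 TPM in the medium-yield and 307 TPM in the high-yield Yangambi library, listed at 0 in the low-yield Yangambi library and at most 0.527 TPM in any LaMe or SP540 library. LOC105041255 was at 211 TPM in the low-yield Yangambi library, 7.49 TPM in the high-yield Yangambi library and under 1 TPM in the other 7. XM_010944754.1 was at 86.9 TPM in the medium-yield Yangambi library and at most 3.58 TPM elsewhere. These features were picked after their values were seen, depth is unknown, and no explanation was tested.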

How the results depend on the processing

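Numbers of called features are given in the order Yangambi against LaMe, SP540 against LaMe, SP540 against Yangambi and any population, and were 176, 129, 14 and 153. They were 64, 54, 0 and 53 with no filter, 429, 235, 60 and 403 with no covariate, which leaves yield class out of the model, and 117, 74, 1 and 100 with transcript rows. With only the 6 libraries compared the pairwise numbers were 52, 39 and 0. Leaving out the low yield class gave 50, 25, 12 and 44, leaving out the medium class 18, 16, 0 and 1, and leaving out the high class 12, 17, 3 and 11. Among alternatives chosen after seeing the data, a pseudocount of 0.1 gave 75 for SP540 against LaMe, 8 for SP540 against Yangambi and 99 for any population, and a pseudocount of 5 gave 5 for SP540 against Yangambi. Leaving out single libraries gave ranges of 27 to 139, 27 to 90, 0 to 21 and 33 to 88. Fits with fewer libraries have fewer residual degrees of freedom than the 4 of the main fit, and the fit with no covariate has more. Numbers in these settings can thus differ through the power of the test alone, and a lower number does not by itself single out a library. How much this accounts for was not tested, nor was the cause with no filter, transcript rows or another pseudocount. Other settings stayed within 1.5 times.

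Yield comparisons gave 0 called features in 96 of 99 alternatives and 1 in 3 (range 0 to 1), each without the low-yield Yangambi library. The variance shares kept their order and their side of the threshold in all 28 values under alternatives, 36.4 to 44.5% for population and 18.4 to 23.8% for yield. With features of at least 10 TPM on average, the correlations of the high to low ratio were 0.135 between LaMe and SP540 and -0.118 between Yangambi and SP540. In the same setting the population ratios correlated between yield classes at 0.377 to 0.477 for Yangambi to LaMe, 0.355 to 0.393 for SP540 to LaMe and 0.145 to 0.307 for SP540 to Yangambi. The cause was not tested.

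Of 287 values of the called named features under alternatives, 70 lost the call and 0 changed sign. LOC105044074, LOC114914524 and LOC105043160 lost it in 0 of 24, LOC105044117 in 1 and LOC105058399 in 2, whereas XR_832332.2 lost it in 9, XM_010920932.3 in 13, and XR_830533.2, XM_010945241.3 and XM_010945243.3 in 15 each. Of genes with a name, adjusted over the list alone, 0 passed in the main fit, and in 12 of 144 values under alternatives 1 or more did. For Yangambi against LaMe they were 2 without the robust step, 3 with no covariate, 2 without the high yield class, 2 without the high-yield Yangambi library and 1 without the low-yield SP540 library, and, chosen after seeing the data, 2 with at least 5 TPM in 3 libraries and 1 with paired genes only. For SP540 against LaMe there was 1 with no covariate, and for SP540 against Yangambi 1 without the high yield class and 1 without the high-yield Yangambi library. For high against low yield they were 4 without Yangambi and 2 without the high-yield Yangambi library. Of 573 values of named features short of the threshold, 0 passed it. The replicate block was population itself, so the fit with no covariate for the yield comparisons is the fit without it. It called 0 features, as did the fit with the block. Planned count tests, count normalizations, gene set tests and the position of medium yield among called features were not run, because the values are TPM, no list had 5 tested genes and no yield feature was called. Unknown depth limits every value near 0.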

Other observations

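LOC105044074 and LOC105044117, both near 0 in LaMe, are directly adjacent among the tested genes on assembly EG11. Their levels were alike, at 67.8 and 68.6 TPM in Yangambi, 73.8 and 73.8 TPM in SP540, and 0.144 and 0.340 TPM in LaMe. In the medium-yield Yangambi library both stood at 102 TPM. Features at 1 TPM or more in 6 libraries and listed at 0 in the remaining 3 numbered 17 for LaMe, 5 for Yangambi and 1 for SP540, and at most 7 for sets of 3 libraries that mixed populations and yield classes, a count made after related values were seen.

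The tests in this part had their predictions written before their own results were seen, but after the counts of called features and the principal components; the test of the variance carried by abundant features, the directions of neighbour pairs, the count with adjacent runs taken once and the balanced splits were added after the results were seen. The pattern weighed first is that population accounted for 37.9% of the variance and yield class for 20.3%. A few abundant features as the cause are argued against only as far as they shift all other features. The 100 most abundant features held 29.2 to 33.5% of TPM. A shift of every feature by the rescaling after their removal would carry 0.229% of the population sum of squares. The 0.126% carried by these features themselves decides little, since 100 of 25145 features on the log2 scale could hardly carry much. Together the values came to 0.356% (0.222 to 0.428% with single libraries left out). The planned removal of these features, which left 36.7%, decides nothing more, since features that carry so little could not bring the share to the predicted 25%. Transcripts of one population that match the reference poorly stay open: 33.3% of the 153 features called for any population (51) were under 1 TPM throughout at least 1 population, which lies between the predicted bounds of 10 and 50. The share among the features tested was 7.81%. That excess decides nothing, since the test favours large differences, which features near 0 in 1 population can show under any cause. Inherited chromosome segments are a candidate explanation that met its prediction. Of the 74 called genes with a place on EG11, 13 had another called gene within 5 tested genes. Random genes of matched expression gave a median of 4, a 95th percentile of 8 and a highest of 16 (permutation p = 0.002). The same number of genes ranked for yield gave 2 (p = 0.8, permutation). However, 4 of the 7 pairs were directly adjacent, where shared reads stay open. The test covers called genes only, not the variance over all features. A batch difference that follows population could not be examined, because the labels give no batches.

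Called genes with called neighbours could also arise from reads shared between adjacent gene copies. Leaving out directly adjacent genes and counting ranks 2 to 10 gave 14 genes with a called neighbour, against a random median of 6 and a 95th percentile of 12 (permutation p = 0.02), and 13 against 6 and 12 with each run of adjacent called genes taken as 1 (permutation p = 0.03), which by a small margin argues against directly adjacent copies as the whole cause. For the 4 directly adjacent pairs, among them LOC105044074 and LOC105044117, shared reads stay open, as population means were positively correlated in all 4 (lowest r 0.7). The same held in 1 of the 3 pairs at ranks 2 to 5 and in 6 of the 8 at ranks 2 to 10. A correlation over 3 means is easily positive between unrelated genes, so these counts decide little. Sequence similarity, and copies several genes apart, were not examined.

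A further hypothesis was that each population carries features of its own, at 1 TPM or more in its 3 libraries and listed at 0 in the other 6. The prediction, set on the population with the fewest, failed: SP540 had 3 such features, and 25 other sets of 3 libraries had at least as many. LaMe and Yangambi had 6 each. For yield class the prediction was set on the class with the most instead. It was met, since 1 mixed set of 78 had as many as the 6 of the low-yield class. Taking the highest of the 3 classes favours that outcome, and the medium-yield and high-yield classes had 5 and 1. LaMe and Yangambi equal the low-yield class, so the opposite outcomes come from the different rules and do not set yield class above population. The median mixed set had 2, so the counts are too small to show more.

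Rearranged labels were used to ask whether other arrangements of the libraries give as many called features. For any population, 1 of 36 rearrangements within yield classes, the real one, reached 153 features, and the highest of the others gave 48. The real arrangement is always among the 36, so no smaller share was possible. The share is under the predicted 0.05, which argues against chance there but cannot exclude it. The pairwise comparisons have 10 splits of the 6 libraries each, too few for a share under 0.05. The fit there was that of all 9 libraries, with the other 3 kept in their group and the second factor as covariate. The real split gave 176 features for Yangambi against LaMe (highest other 0, 1 of 10 splits as large), and 129 for SP540 against LaMe and 14 for SP540 against Yangambi (highest other 1 and 1 of 10 splits as large in each). Among the 4 splits that kept 1 library of each yield class on either side, the highest other was 0, 0 and 1. For the yield comparisons the real number is 0, which all 36 rearrangements for any yield class and all 10 splits of each pairwise comparison reach whatever the labels, so these say nothing about chance. The highest other there was 1 in each.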
